A study of Mus musculus with 8 samples.

How the data were processed

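RNA of 8 liver samples from male mice of strain C57/B6 aged 2 months was measured on Illumina bead arrays, 1 array per sample. Per the labels, the 4 genotypes had 2 samples each. The WT samples carried floxed alleles of Pten and Shp2 without Alb-Cre. SKO, PKO and DKO carried Alb-Cre, a recombinase under the albumin promoter that deletes floxed DNA in hepatocytes, with deletion of Shp2, of Pten and of both genes. The Cre transgene was therefore absent only from WT, so its own effect cannot be told apart from that of the deletions in comparisons with WT, and it enters the interaction with its sign reversed. Per the labels' protocols, RNA was extracted with a column kit, checked by capillary electrophoresis, and turned into biotinylated cRNA with an Ambion MessageAmp kit. The labels do not say that the samples of a group came from separate animals, so p-values measure the spread between these samples, which may be partly technical.

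The deposited values are of 3 kinds. The deposited series table holds probe intensity on a linear scale, and its columns share 1 distribution, which shows quantile normalization between arrays by the authors with no background subtracted; each column's median was between 250.9 and 251.3. The deposited scanner table holds the average bead intensity per probe before normalization, per the file headers. It also holds a detection p-value per probe and array, per the file headers, which sets the probe against the array's negative controls. The submitters' processing notes name GenomeStudio and give no version. Other upstream steps are not given in the sources used here.

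The scanner table names its columns by position on 1 slide. The same position stands on the labels of WT replicate 1 and DKO replicate 2, and another position stands on none. The columns of these 2 positions, 4 in number, were not used in any step. For the other 6 arrays the order of probes by scanner signal and by deposited normalized value was identical (Spearman correlation of 1). The normalized table of all 8 arrays was therefore the main source, as the design fixed before the data were examined provided for columns that could not be tied to samples by their names. All named columns lie on 1 slide, so a slide effect could not be fitted. Because background was not subtracted, folds are smaller than the changes in RNA, most of all for dim probes: the background level of the 6 arrays was 213 to 222 in scanner units, against array medians of 240 to 261. The scanner signal at the 75th percentile was 487 on WT replicate 2, 556 and 533 on SKO, 489 and 498 on PKO, and 707 on DKO replicate 1. Quantile normalization removes such differences, whether they are technical or biological.

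Values were taken to log2. The design asked for a detection p-value under 0.01 on at least 2 of 8 arrays. As that p was usable on 6 arrays, a common normalized intensity of 285.009 took its place. This is the median over those arrays of the lowest normalized intensity with detection p under 0.01, which ranged from 263.985 to 297.332. A probe was kept when at least 2 of the 8 arrays reached it. Of 25697 probes, 23978 had 1 gene symbol in the platform annotation, 1719 had none and 0 had several; 0 symbols changed when updated through their Entrez identifiers. The filter kept 11508 probes, of which 10815 had a symbol. Each gene was represented by its probe with the highest mean, which gave 8148 genes. Genes are named by symbol. No genome build is named by the files, so no coordinates are given.

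Differences were tested with limma 3.58.1 in R 4.3.3: lmFit on the 4 genotype means over all 8 arrays, then eBayes without trend or robust options, two-sided. The fit had 4 residual degrees of freedom, and 9.69 after moderation. P-values were adjusted by Benjamini-Hochberg over the genes of a comparison, with a threshold of 0.05. A positive log2 fold change means higher in the group named first. The interaction is DKO minus PKO minus SKO plus WT, the departure of the double deletion from the sum of the single deletions on the log2 scale. The errors beside log2 fold changes are standard errors from this fit, with 2 arrays per group. Where all probes of a gene fell short of the detection level on every array of a group, the fold is a bound ("at least"): the mean of the brighter group against the mean of, per array, the higher of the detection level and the probe's own signal. The same bound was used for Gpnmb in DKO against WT, where the probe used, but not every probe of the gene, fell short of the level in WT.

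Before the data were examined, 29 gene lists with 625 genes were fixed; 557 of the genes had a named probe and 422 were tested. They cover lipogenesis, lipid droplets and lipid uptake, fatty acid oxidation by PPARa, cholesterol synthesis, bile acid synthesis, bile acid transport and FXR, gluconeogenesis and FoxO targets, collagen and matrix, macrophages, cytokines and chemokines, neutrophils, T and NK cells, B cells and antigen presentation, cholangiocytes and progenitors, oncofetal and tumour genes, the cell cycle, ERK and AP1 targets, the acute phase, male-biased and female-biased liver genes, xenobiotic cytochromes, NRF2 and glutathione, the unfolded protein response, mature hepatocytes, pericentral and periportal zonation, liver endothelium, erythroid cells, and pancreas, adipose or muscle. Each was tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, with camera at an estimated correlation and fry beside it. The fry test asks whether a list's genes move on balance one way, and does not set the list against other genes.

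The rule for named genes was also fixed then: Ptpn11 and Pten; the 10 largest rises and falls among called genes of each comparison with WT and of the interaction, with no overlap between the arrays of the groups for the former, and 5 each way for DKO against PKO and DKO against SKO; up to 4 called members per list in each comparison with WT, by adjusted p; and 25 genes of liver metabolism, fibrosis, inflammation and growth whatever their result. Of the last, Gck and Spp1 had no named probe, and Nr0b2, Cd36, Ccl2, Tnf, Prom1, Sox9, Afp and Myc were below the detection filter. In the report, examples were taken first from named genes whose call held when each array was left out in turn, a choice made after seeing the data.

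The fits were tested on simulated data before use. With 200 of 8148 genes changed, the share recovered for SKO against WT was 23.9% at a true log2 change of 0.5, 89.6% at 1 and 100% at 2, with 6 false calls. For DKO against WT these shares were 25.4%, 97% and 100%, with 7 false calls, and for the interaction 1.49%, 65.7% and 98.5%, with 2 false calls. A list shifted by 0.5 on DKO against WT was called by camera at both correlations. At the preset correlation 0 other lists were called, and at the estimated one other lists were not counted. Genes were simulated as independent, so this does not show how often camera calls lists of correlated genes falsely. In the data, estimated correlations were 0.21 for collagen and matrix, 0.73 for macrophage and -0.06 for gluconeogenesis and FoxO genes.

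Alternatives fixed beforehand were normexp background correction with an offset of 50, cyclic loess, neqc on the scanner signals, 3 other detection filters, the mean of a gene's probes, eBayes with trend and robust options, fits of only the groups compared, the replicate number as a block, each array left out, and the other list tests. With an array left out, its group has 1 sample, which is assumed to vary like the other groups. Scanner signals of 6 arrays scaled to a common median, the deposited values of those 6 arrays, and a filter on their detection p were added after seeing the data, as was a split of the WT arrays, in which each of 2 comparisons that share WT used its own WT array. Figures were drawn with matplotlib 3.10.9.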

Results

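Gene expression was measured in livers of 2-month-old male mice of 4 genotypes, with 2 samples each: WT, with neither gene deleted; SKO, with hepatocyte deletion of Shp2, the tyrosine phosphatase that the gene Ptpn11 encodes; PKO, with hepatocyte deletion of Pten, the lipid phosphatase that opposes PI3K signalling; and DKO, with both deleted. The design sets each deletion against WT and the double deletion against each single one. After the detection filter, 8148 genes were compared. About 40.5% of probes passed the detection level on each array, a share made equal by the common level and the shared distribution of the arrays. Scanner signals passed a detection p of 0.01 for 9937 probes on WT replicate 2, 10631 and 10426 on SKO, 10058 and 10404 on PKO, and 11615 on DKO replicate 1. The number of arrays limits the precision of every comparison. Across genes, log2 values of the arrays of a group correlated at r of 0.988 to 0.992, and arrays of different groups at 0.922 to 0.981; genes are not independent replicates. The first principal component held 58.5% of the variance and placed the DKO arrays at 37.8 and 30.9, the WT arrays at -19.6 and -22.1, and the other arrays between -10.0 and -4.61. The second, with 14.3%, placed SKO at -15.9 and -15.8 and PKO at 12.4 and 12.8.

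Ptpn11 was lower in the genotypes with Shp2 deletion. Its log2 signal was 12.84 ± 0.06 in WT, 11.62 ± 0.12 in SKO, 12.83 ± 0.19 in PKO and 11.58 ± 0.17 in DKO (mean ± SD, n = 2 each). It fell by 1.22 on the log2 scale in SKO (SE 0.14, limma adjusted p = 0.00142) and by 1.27 in DKO (adjusted p = 0.00016), and differed by -0.01 in PKO (adjusted p = 0.98). Both SKO arrays and both DKO arrays lay below all WT and PKO arrays, on this probe and on both other detected Ptpn11 probes. Other cells of the liver keep the gene, and whether the probes lie in the deleted part is not stated. On background-corrected scanner signals of 6 arrays the difference in SKO was -1.33 with an adjusted p of 0.114. Pten had no named probe, so that deletion could not be checked.

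**Figure D1:**
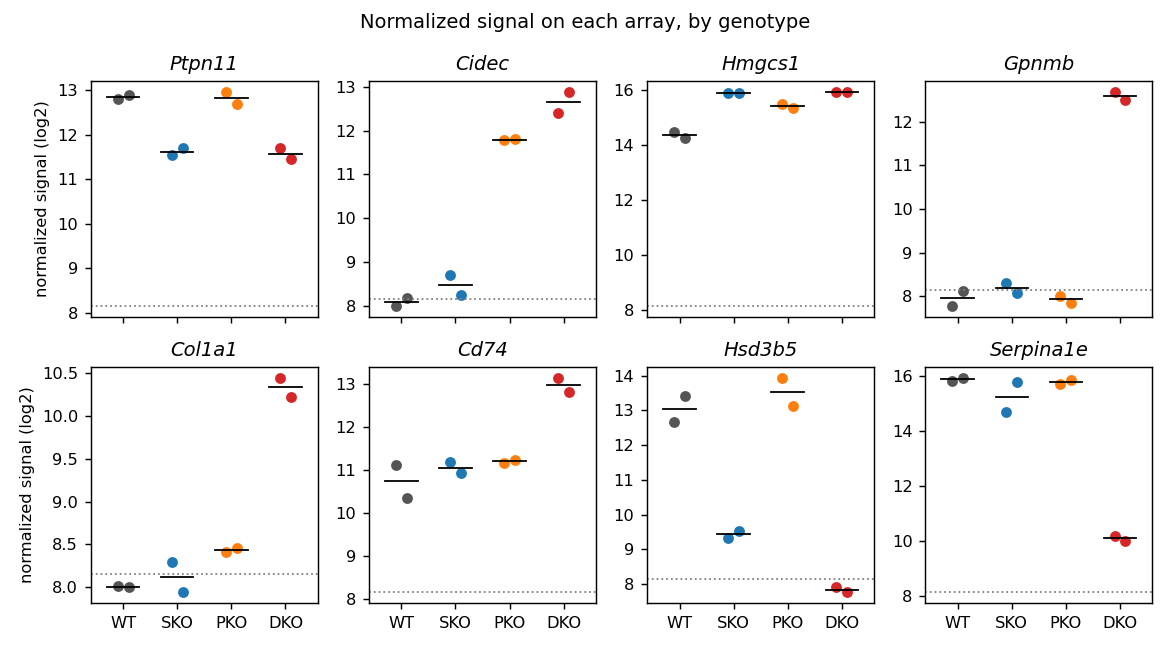
Normalized signal (log2, y axis) of 8 named genes on each array (points) by genotype (x axis), with 2 arrays per genotype; black bars are group means and the dotted line is the detection level. Ptpn11 lies lower in SKO and DKO, Cidec higher in PKO and DKO, Gpnmb, Col1a1 and Cd74 higher in DKO, Hsd3b5 lower in SKO and DKO, and Serpina1e lower in DKO, at 10.11 against 15.89 in WT.

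In SKO against WT, which asks what deletion of Shp2 alone changes, Spon2, which encodes a secreted matrix protein, rose 5.33-fold (log2 2.41 ± 0.20 SE, limma adjusted p = 0.000281), and Csad, an enzyme of taurine synthesis, rose 4.65-fold (log2 2.22 ± 0.17, adjusted p = 0.00028). Pparg, a nuclear receptor of lipid storage, rose 2.34-fold (log2 1.22 ± 0.12). The clock repressor Nr1d1 rose 3.36-fold (log2 1.75 ± 0.25, adjusted p = 0.00477, and 0.0523 without WT replicate 1). Hsd3b5, a male-biased steroid dehydrogenase, fell by 3.61 on the log2 scale (SE 0.28, adjusted p = 0.00028). Falls were also seen in Thrsp, a regulator of lipogenesis (log2 -2.53), Serpina12 (-2.54) and Hamp2, a hepcidin gene (-2.68). Scara5, a ferritin receptor, was at least 8.05-fold lower. Dimmer probes of Serpina12 and Pparg differed by -0.26 and 0.24. The glucocorticoid-induced gene Fkbp5 fell by 2.35 on the log2 scale in SKO and by a similar amount in PKO, at -1.99 (adjusted p = 0.00723, and 0.0865 without WT replicate 1). Dusp6, a feedback phosphatase of ERK, fell by 1.64, but this call was lost without WT replicate 1 (adjusted p = 0.086), WT replicate 2 (0.0766) or SKO replicate 2 (0.0544). The AP1 member Junb rose (log2 1.27), while Egr1 differed by 0.75 (adjusted p = 0.118), Jun by -0.000756 (adjusted p = 0.999) and Ccnd1 by 0.21 (adjusted p = 0.537).

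In all, 345 of 8148 genes changed in SKO against WT, 212 higher and 133 lower, and 118 of them by at least 2-fold. The count was 118 without WT replicate 1, 128 without WT replicate 2 and 142 without SKO replicate 1. On 6 arrays it was 159 with the deposited values and 16 with background-corrected scanner signals; with scanner signals scaled by the median it was 222, of which 79.7% were higher, against 61.4% of the 345, with the median of all genes moved by 0.13. Of the 60 named genes called here, 21 kept their call in all 8 fits that left out an array.

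Cholesterol synthesis genes had the lowest camera p among the lists in SKO. Of 18 tested, 5 rose and 0 fell (median log2 fold change 0.73; 11 rose when adjusted over the list alone), among them Hmgcs1, the cytosolic HMG-CoA synthase (2.9-fold, log2 1.53 ± 0.12), Mvd (log2 1.24) and Cyp51 (log2 1.16). The camera adjusted p was 6.88e-08 at the preset correlation and 0.578 with an estimated correlation. The count of risen members was 2 without WT replicate 1, 1 without WT replicate 2, 10 without SKO replicate 1 and 3 without SKO replicate 2 or without either PKO array; Mvd lost its call without WT replicate 2 (adjusted p = 0.0916) and Cyp51 without WT replicate 2 (0.0916) or WT replicate 1 (0.077). Hmgcs1 lay near the top of the intensity scale in SKO and DKO (log2 15.9), which compresses its fold.

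NRF2 and glutathione genes, which serve antioxidant defence, had the second lowest in SKO, with 4 of 23 risen (10 adjusted over the list alone; median 0.35; camera adjusted p = 1.05e-06, and 0.578 with an estimated correlation). Gsta1 (3.04-fold), Gclm, Gpx4 and Ephx1 were the members, but each lost its call without WT replicate 1 and without SKO replicate 1. The log2 difference of Gsta1 was 1.56 and 1.42 in those fits. Collagen and matrix (3 of 28 rose: Lum, Col5a1 and Col4a1; adjusted p = 0.672 with an estimated correlation) and oncofetal and tumour genes (2 of 12 rose: Anxa5, log2 1.44, and Igf2bp3, at least 1.72-fold; 0.578) also passed camera, as did erythroid genes (1 of 3 rose: Hba-a1; 0.578). Macrophage genes (median 0.43; 0.713) and B cell and antigen presentation genes (median 0.30; 0.713) passed it with 0 members called (5 and 0 adjusted over the list alone). Without WT replicate 2 the camera call was lost for collagen (adjusted p = 0.0666), macrophages (0.051), oncofetal genes (0.051), erythroid genes (0.0912) and antigen presentation (0.557). Erythroid genes and antigen presentation lost it too without SKO replicate 1 (0.123 and 0.23) and without either PKO array (0.0593), and erythroid genes without SKO replicate 2 (0.0509). Without WT replicate 2, Col5a1, Col4a1, Lum, Hba-a1 and Igf2bp3 had adjusted p of 0.242, 0.268, 0.208, 0.126 and 0.12, and they lost their calls without some other arrays as well.

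The other lists did not pass camera in SKO. Among lipogenic genes, 1 of 21 rose and 3 fell: Elovl5 rose (log2 0.90), and Thrsp, Lpin1 (-2.79) and Dgat2 fell, with Fasn at 0.18 (adjusted p = 0.592), Scd1 at -0.03 (0.928) and Srebf1 at -1.05 (0.0564, and 0.0332 without either PKO array). The calls of Elovl5, Lpin1 and Dgat2 were lost when single arrays were left out, at adjusted p up to 0.0667, 0.125 and 0.193. Bile acid transport had 3 of 13 risen, led by Abcb11, the bile salt export pump (log2 0.89, adjusted p = 0.00419); the count was 1 without either WT array or SKO replicate 1. Male-biased liver genes split, with 2 of 17 higher, including Cyp4a12b (3.08-fold), and 3 lower. The list passed camera as lower without WT replicate 1 (adjusted p = 0.0134) or SKO replicate 2 (0.038). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, differed by 1.07 (adjusted p = 0.227), Cyp8b1 by 0.96 (0.484, and 0.0185 without either DKO array), Adgre1 by 0.36 (0.485), Cidec by 0.39 (0.301), Igfbp1 by 0.16 (0.75) and Pck1 by -0.07 (0.868). Col1a1 (adjusted p = 0.713) and Timp1 (0.695) were under the detection level in WT, so small differences could not have been seen. Mature hepatocyte and endothelial lists had 0 members called, with medians of -0.08 and -0.03, though endothelial genes passed camera as higher without WT replicate 1 (adjusted p = 0.00144) and as lower without WT replicate 2 (9.98e-05). They also passed as higher in the 3 settings of 6 arrays, which lack WT replicate 1.

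PKO against WT asks what deletion of Pten alone changes. Lipid droplet genes were among those higher in PKO. Cidea was at least 16.9-fold higher, and Cidec, its relative on lipid droplets, rose 13.1-fold (log2 3.72 ± 0.19 SE, limma adjusted p = 1.84e-05). Apoa4, an apolipoprotein, rose 8.24-fold (log2 3.04 ± 0.17), and Pparg rose 4.3-fold (log2 2.10 ± 0.12). Of 18 genes of lipid droplets and lipid uptake, 9 rose and 0 fell (median 0.78; 10 adjusted over the list alone; camera adjusted p = 1.01e-09, and 0.498 with an estimated correlation; fry adjusted p = 0.0324). That count was 5 without WT replicate 1 and 5 without PKO replicate 1. Further rises were seen in Clstn3 (8.06-fold), Spon2 (6.13-fold), Tubb2b (5.28-fold), Wfdc2 (5-fold) and Ntrk2 (at least 3.28-fold). Nr1d1 rose 3.32-fold (adjusted p = 0.00626, 0.0734 without WT replicate 1 and 0.0634 without PKO replicate 1), and differed by log2 0.47 in DKO (adjusted p = 0.178, and 0.0321 without DKO replicate 1). Eif4ebp3, a translation repressor, was at least 4.45-fold lower. Dimmer probes moved less: 0.60 for Pparg, 0.60 and 0.04 for Tubb2b, and 0.91 for Wfdc2. Falls were seen in the metallothionein Mt1 (log2 -1.97), Susd4 (-1.89), Nrg4 (-1.76), Scara5 (-1.67) and the clotting factor gene F7 (-1.03).

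Several calls in PKO were lost when single arrays were left out, while the differences kept their direction. Fgf21, a hepatokine, rose 6.22-fold (log2 2.64, adjusted p = 0.00956). Its log2 difference was 2.55 without WT replicate 1 (adjusted p = 0.0909), 2.72 without WT replicate 2 (0.0569) and 2.07 without PKO replicate 1 (0.0841). Igfbp2 fell by 2.35 (adjusted p = 0.00813); it was at -2.16 without WT replicate 1 (0.087) and -2.17 without PKO replicate 1 (0.0853). Cyp7a1 fell by 2.04 (adjusted p = 0.0365). It was at -1.30 without WT replicate 1 (0.188), -1.58 without PKO replicate 1 (0.25) and -2.505 without PKO replicate 2 (0.0575). In all, 339 genes changed, 196 higher and 143 lower, 97 of them by at least 2-fold. The count was 54 without WT replicate 1, 139 without WT replicate 2, 56 without PKO replicate 1 and 144 without PKO replicate 2. It was 512 in a fit of only these groups. On 6 arrays it was 59 with the deposited values, 50 when scanner signals were scaled by the median (72% higher, against 57.8%) and 2 with background correction (100% higher). Of the 56 named genes called, 21 kept their call in all 8 fits without an array.

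Other lists past camera in PKO were oncofetal and tumour genes, with 4 of 12 risen (Anxa2, 3.63-fold, Anxa5, 2.42-fold, Lgals1 and S100a11; adjusted p = 0.498 with an estimated correlation), NRF2 and glutathione genes with 3 of 23 (10 adjusted over the list alone; 0.498), lipogenesis with 3 of 21 (Elovl5, Me1 and Acly; 10 adjusted over the list alone; 0.499), collagen and matrix with 1 of 28 (Loxl1; 0.498) and antigen presentation with 0 of 8 (0.554). Xenobiotic cytochromes fell as a list, with Cyp1a2, Cyp2c50, Cyp2c37 and Cyp2a5 lower among 17 (4 adjusted over the list alone; median -0.15; camera adjusted p = 0.0347, and 0.498 with an estimated correlation), and its camera call was lost without WT replicate 1 (adjusted p = 0.149) or PKO replicate 1 (0.107), with background-corrected scanner signals (0.261) or deposited values (0.128) of 6 arrays, and narrowly without either SKO array (0.0509). Oncofetal genes had 2 risen without either PKO array, NRF2 genes had 0 without either WT array and 1 without either PKO array, and Loxl1 lost its call without any WT or PKO array. Lipogenesis had 1 risen without any single WT or PKO array and 6 without either SKO array, and lost its camera call without WT replicate 2 (0.182) or PKO replicate 2 (0.14). Without WT replicate 2 the calls of collagen (0.13) and antigen presentation (0.525) were also lost, and that of antigen presentation without PKO replicate 1 (0.117) and either SKO array (0.0509). Xenobiotic members called numbered 0 without WT replicate 1 and 1 without PKO replicate 1.

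Among genes fixed beforehand, Fasn differed by 0.63 in PKO (adjusted p = 0.067, and 0.0262 without either SKO array), Scd1 by 0.44 (0.126), Srebf1 by -0.37 (0.474), Pck1 by -0.08 (0.857), Cyp8b1 by 0.30 (0.859), Adgre1 by 0.33 (0.53), Jun by 0.29 (0.226) and Egr1 by -0.31 (0.524). Col1a1 (adjusted p = 0.131) was under the detection level in WT, Igfbp1 (0.346) in PKO and Timp1 (0.992) in both, so small differences in them could not have been seen. Hmgcs1 rose 2.07-fold and Elovl3 2.47-fold. Tk1, the S-phase thymidine kinase, fell by 1.10, a call lost with the mean of its probes (adjusted p = 0.0931), and Ccnd1, cyclin D1, fell by 0.87 (adjusted p = 0.0217, and 0.169 without PKO replicate 1; lost too without PKO replicate 2 or WT replicate 1). Macrophage genes (median 0.08) and endothelial genes (0.13) had 0 members called. The endothelial list passed camera as higher without WT replicate 1 (adjusted p = 2.45e-05) and in the 3 settings of 6 arrays, and as lower without WT replicate 2 (0.00774).

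**Figure D2:**
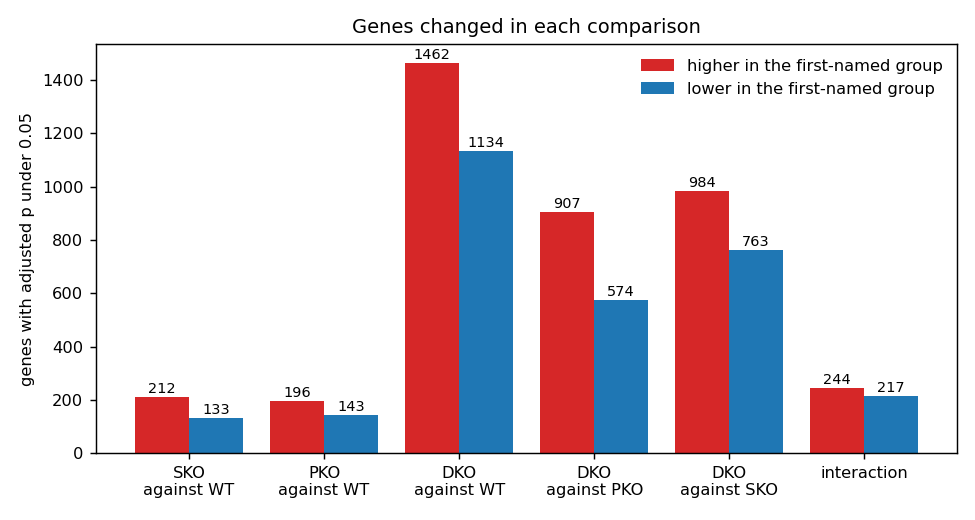
Number of genes with limma adjusted p under 0.05 (y axis) in each comparison (x axis), among 8148 tested; red bars are higher and blue bars lower in the group named first, and for the interaction above or below the sum of the single deletions. DKO against WT had 1462 higher and 1134 lower genes, against 212 and 133 for SKO and 196 and 143 for PKO.

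DKO against WT asks what deletion of both genes changes. At the preset correlation some lists passed camera and others did not, and with an estimated correlation 0 lists passed. Gpnmb, a glycoprotein of lipid-laden macrophages, was at least 21.8-fold higher by its brightest probe (limma adjusted p = 4.85e-07), while its other 3 detected probes differed by log2 0.15, 0.57 and 0.46, with DKO means of 8.18, 8.40 and 8.27 near the detection level of 8.15. Lgals3 rose by 4.17 ± 0.28, while the acute-phase lipocalin Lcn2 rose 14.8-fold. Sdcbp2 was at least 25.2-fold and Ly6d at least 20.1-fold higher. S100a11 rose 21.9-fold, Spon2 21.1-fold, Tubb2b 20.9-fold, Wfdc2 19.8-fold and Anxa2 16.3-fold. Serpina1e, an alpha-1 antitrypsin of hepatocytes, fell by 5.77 ± 0.27, from a log2 signal of 15.89 ± 0.07 to 10.11 ± 0.13 (SD, n = 2 each). Its WT signal lay near the top of the scale (log2 16.02), where differences are compressed, so this fall and those against PKO and SKO are not exact. Hsd3b5 was at least 29.5-fold lower. Sult2a8, a bile acid sulfotransferase (log2 -5.08), Ppp1r3c (-3.41), Igfbp2 (-3.20), Apom, an apolipoprotein (-3.13), and Fgf1 (-2.95) fell as well.

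DKO differed from WT in 2596 of 8148 genes, 1462 higher and 1134 lower, 636 of them by at least 2-fold. The count was 1596 without WT replicate 2 and 1684 without DKO replicate 1, and on 6 arrays 1427 with deposited values (65.5% higher) and 953 with background correction (71.1% higher). The balance of directions depended on the scaling: 56.3% of the 2596 genes were higher, and 91% of 2358 when scanner signals were scaled by the median, which moved the median of all genes by 0.33. Of 112 named genes called, 98 kept their call in all 8 fits without an array. Dimmer detected probes of some named genes moved less than the ones used: Clec7a (log2 0.48 and 0.50), Pparg (0.40), Sdcbp2 (2.84 and 1.46), Wfdc2 (2.23), Cyp2c37 (-0.47 for 1 of 2), Cyp2c50 (-0.94), Tk1 (-0.35 and -0.31), Cdkn1a (1.01 and 0.40), Ccnd1 (0.14 for 1 of 2) and Tubb2b (1.04 for 1 of 2). These were chosen after their values were seen. Different probes of 9 genes were called in opposite directions, among 2011 genes with several probes.

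Matrix genes rose in DKO nearly throughout the list. Of 28 collagen and matrix genes, 26 rose and 0 fell (median 1.32; 26 adjusted over the list alone; camera adjusted p = 1.04e-16, and 0.223 with an estimated correlation). Col1a1, a chain of fibrillar collagen, was at least 4.51-fold higher (adjusted p = 4.9e-06), Col3a1 at least 3.3-fold, the protease inhibitor Timp1 at least 3.43-fold, while Col4a1 rose 4.97-fold and Loxl1, a collagen crosslinker, 4.81-fold. Oncofetal and tumour genes showed 9 risen and 1 fallen of 12 (median 1.58; 10 risen adjusted over the list alone; 0.223 with an estimated correlation), with the fall of that gene lost without WT replicate 1, either PKO array or either DKO array.

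Markers of immune cells were also higher. Of 20 macrophage genes, 16 rose and 0 fell (median 1.63; 18 adjusted over the list alone; camera adjusted p = 5.7e-10, and 0.274 with an estimated correlation), among them Clec7a (3.38-fold), Ms4a7 (at least 2.77-fold) and Adgre1, which encodes F4/80 (3.96-fold, adjusted p = 0.00042). Of 8 genes of B cells and antigen presentation, 7 rose (median 1.63; 7 adjusted over the list alone; 0.228 with an estimated correlation), led by the class II genes H2-Eb1 (4.14-fold), H2-Ab1 (4.11-fold) and H2-Aa (3.84-fold) and their chaperone Cd74 (4.72-fold). Endothelial markers, by contrast, had 0 of 18 called (median 0.14; camera adjusted p = 0.625), although 6 rose without WT replicate 1 (list adjusted p = 0.00754), 5 rose with the deposited values of 6 arrays (0.00121), and 2 fell without WT replicate 2. Cytokines and chemokines had 6 risen, including Icam1 (2.88-fold) and Cxcl16 (2.62-fold), and 2 fallen of 16 (0.445 with an estimated correlation); the camera call was lost without WT replicate 2 (adjusted p = 0.0627) or DKO replicate 1 (0.0955), and the fallen count was 0 or 1 without a WT or DKO array. Of 6 neutrophil genes, S100a8 and S100a9 were called, at least 6.5-fold and 3.23-fold higher, with both calls lost without WT replicate 1 (adjusted p = 0.0882 and 0.116) or WT replicate 2 (0.102 and 0.151), and that of S100a9 also without either SKO array (0.0533) or either PKO array (0.0567). The list did not pass camera, except without DKO replicate 2 (adjusted p = 0.000459, 4 risen). T and NK cell genes had 1 of 5 called (Thy1, lost without WT replicate 2, adjusted p = 0.0666), and cholangiocyte and progenitor genes 3 of 6 (Bicc1, 3.56-fold, Tspan8, and Anxa13, which lost its call without WT replicate 2, adjusted p = 0.15, or DKO replicate 1, 0.139), neither list past camera.

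Of the lists of lipid metabolism and antioxidant defence, lipid droplet and NRF2 genes rose in DKO. Of 18 genes of lipid droplets and uptake, 11 rose and 0 fell (median 1.32; 14 adjusted over the list alone; camera adjusted p = 7.91e-08, and 0.223 with an estimated correlation): Cidec 23.6-fold, Apoa4 19.4-fold, Cidea at least 11.3-fold and Pparg 3.28-fold. NRF2 and glutathione genes had 16 of 23 risen and 0 fallen (median 1.07; 18 adjusted over the list alone; 0.223 with an estimated correlation), with Gsta1 at 12.2-fold, Cbr3 at 10.4-fold and Gpx4 at 3.5-fold by their brightest probes. The second Cbr3 probe differed by log2 1.55 and the second Gpx4 probe, near the detection level in all groups, by 0.20. Lipogenic genes went both ways (9 risen and 4 fallen adjusted over the list alone), with 8 risen (4 without WT replicate 2) and 4 fallen of 21: Me1 and Acaca rose 3.07-fold and 2.5-fold, Mlxipl fell by 1.19, and Fasn rose 1.68-fold (adjusted p = 0.00753, and 0.0547 without WT replicate 2). Scd1 was called at 1.37-fold (adjusted p = 0.0357), a call lost in 5 of the 8 fits without an array (adjusted p up to 0.236) and with cyclic loess. Scd1 lay near the top of the scale in all groups, at log2 15.26 in WT and 15.72 in DKO, and Elovl5 in PKO and DKO, at 15.64 and 15.84, so their changes are understated and a small one may be missed in any comparison. Aldh3a2 in DKO (15.59), Cyp2a5 in SKO and DKO (15.74 and 15.66) and Cyp8b1 in SKO (15.61) lay there too. Cholesterol synthesis had 6 risen (3 without WT replicate 2 or DKO replicate 2) and 1 fallen of 18, and oxidation genes 5 risen (10 without DKO replicate 1) and 4 fallen of 24 (2 without WT replicate 2 or DKO replicate 1), including Fgf21 (10.9-fold) and Pdk4 (3.05-fold); neither list passed camera.

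Hepatocyte transcripts of several kinds were lower in DKO. Male-biased liver genes had 11 of 17 fallen and 0 risen (median -1.23; 13 adjusted over the list alone; camera adjusted p = 7.91e-08, and 0.223 with an estimated correlation), among them Ugt2b1 (-1.79) and Elovl3 (at least 2.4-fold lower), while of 6 female-biased genes 1 was called, Ntrk2, at least 5.59-fold higher. Mature hepatocyte genes had 10 of 21 fallen (median -0.33; 11 adjusted over the list alone; 0.223 with an estimated correlation), with F7 at -2.33 and Hpd at -1.81. Periportal genes had 10 of 14 fallen (6 without WT replicate 2; 10 adjusted over the list alone; median -0.68; 0.223), led by Hal, histidine ammonia lyase (-2.81), and Hsd17b6 (-1.95). Xenobiotic cytochromes had 9 fallen (3 without WT replicate 1, 5 without WT replicate 2) and 1 risen of 17 (median -0.38; 0.274), with Cyp2c37 at -2.47 and Cyp2c50 at -2.57; with background-corrected scanner signals of 6 arrays the list's adjusted p was 0.0924. Pericentral genes had 4 fallen and 1 risen of 13 (median -0.44; 0.274), with Slc1a2 at -2.10 and Aldh3a2 at 1.61; the camera call was lost without WT replicate 2 (adjusted p = 0.0627) or DKO replicate 1 (0.0643).

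Bile acid transport and FXR genes had 5 fallen and 2 risen of 13 (median -0.27; camera adjusted p = 0.0294, and 0.274 with an estimated correlation): the sterol transporters Abcg8 and Abcg5 fell (log2 -2.82 and -2.05), and Slc51b, a basolateral bile acid exporter, was at least 4.06-fold higher. This list's adjusted p was 0.0924 on background-corrected scanner signals and 0.0757 on deposited values of 6 arrays, 1 member rose without any single WT, PKO or DKO array, and its median was 0.18 when signals were scaled by the median, below the all-gene median of 0.33. Bile acid synthesis had 4 fallen and 2 risen of 13, with a median of 0.01, a mean of -0.47 and no camera call (adjusted p = 0.21), except without DKO replicate 2 (0.0306); Cyp7b1 fell by 2.77, and Cyp7a1 differed by 0.25 (adjusted p = 0.698; -0.49 without WT replicate 2). Cyp8b1 differed by -1.31 (0.172); it was called at -2.77 without DKO replicate 2 (4.51e-05) and on 6 arrays, and was at 0.15 without DKO replicate 1. Gluconeogenesis and FoxO targets had 4 fallen (2 without WT replicate 2 or DKO replicate 2) and 1 risen of 14 (median -0.31; 0.223 with an estimated correlation), with a list adjusted p of 0.118 among genes detected on all 8 arrays; Got1 was at -1.47 and Pck1, the gluconeogenic PEP carboxykinase, at -0.72 (adjusted p = 0.0129, 0.105 without WT replicate 2 and 0.0645 without DKO replicate 2). Unfolded protein response genes had 4 of 19 fallen (0.34 with an estimated correlation), but 0 without WT replicate 2, where the list's adjusted p was 0.0648, and 2 without WT replicate 1 or DKO replicate 2. Cela1 was the member of the pancreas, adipose and muscle list that fell (-1.55), of 5 tested (0.274 with an estimated correlation; list adjusted p = 0.0514 without WT replicate 1). Srebf1 differed by -0.55 (0.14) and Igfbp1 by -0.13 (0.687), and erythroid genes had 0 of 3 called.

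Cell cycle genes in DKO had 12 risen (7 without WT replicate 2) and 1 fallen of 19 (median 0.75; 13 risen adjusted over the list alone; camera adjusted p = 0.000399, and 0.274 with an estimated correlation; 0.112 among genes detected on all 8 arrays). Ccnd1 rose 2.28-fold and the cell cycle inhibitor gene Cdkn1a 2.67-fold, whereas Tk1 fell by 1.83. ERK and AP1 targets had 7 risen (4 without DKO replicate 1) and 3 fallen (1 without WT replicate 1, WT replicate 2 or DKO replicate 2) of 14, with no camera call (adjusted p = 0.0826) except without DKO replicate 2 (0.0297); Jun rose 2.56-fold, Klf6 4.99-fold and Egr1 2.26-fold (adjusted p = 0.00504), and Phlda1 fell by 1.86. Acute-phase genes had 6 risen and 4 fallen (2 without either WT array) of 21: Orm2 rose 14.2-fold and Saa2 3.31-fold, and Saa4 fell by 2.05. This list did not pass camera (adjusted p = 0.359).

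**Figure D3:**
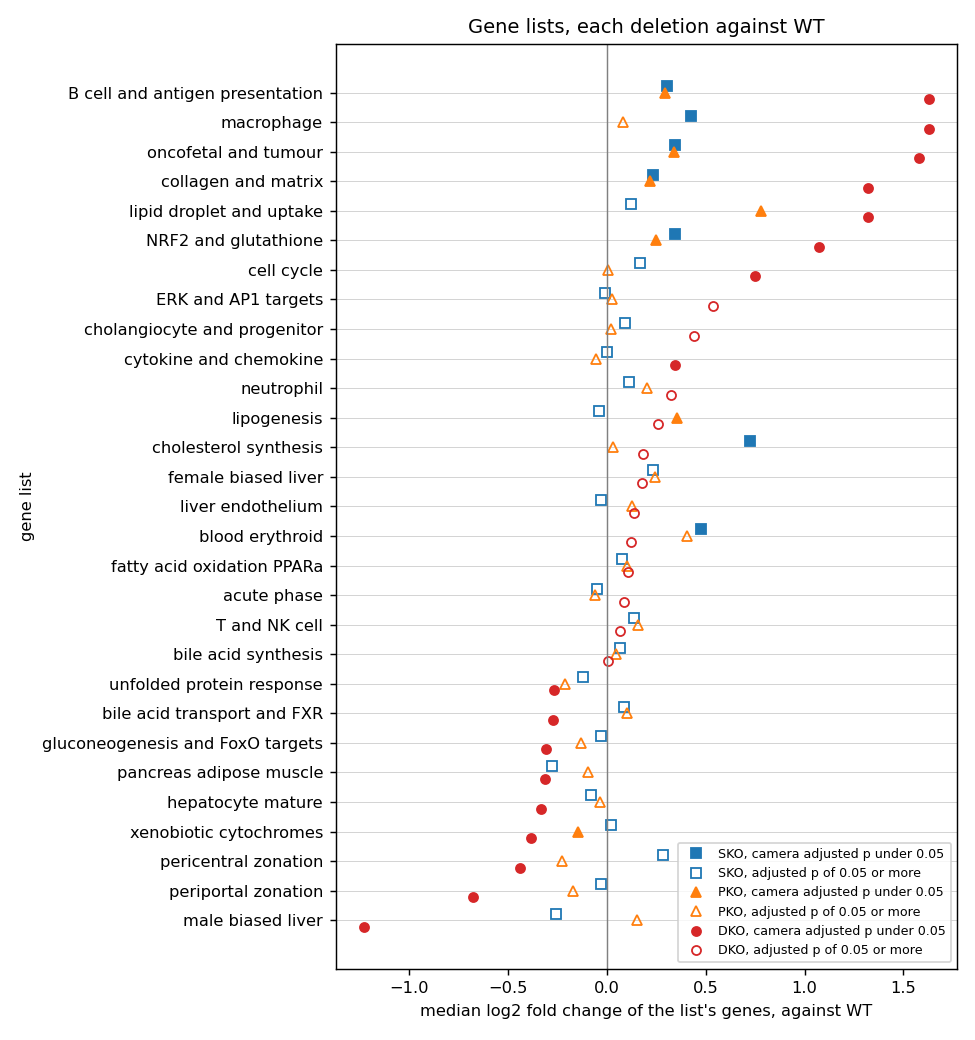
Median log2 fold change against WT (x axis) of the genes of each of 29 lists (y axis), for SKO (squares), PKO (triangles) and DKO (circles), with 2 arrays per genotype; filled symbols passed camera at the preset correlation of 0.01, and 0 lists passed with an estimated correlation. DKO medians run from -1.23 for male-biased liver genes to 1.63 for macrophage and antigen presentation genes, while those of SKO and PKO lie between -0.28 and 0.78.

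Against PKO, the double deletion shows what Shp2 loss changed where Pten was also lost. Gpnmb was at least 21.8-fold higher in DKO, Lcn2 19.2-fold, Sdcbp2 13.9-fold, Orm2 13.4-fold and Lgals3 12.2-fold. Falls were seen in Serpina1e (log2 -5.69), Sult2a8 (-4.93), the regulator of G-protein signalling Rgs16 (-4.30) and Serpina4-ps1 (-3.35), and Hsd3b5 was at least 41.2-fold lower. Of 28 matrix genes 25 rose, and of 20 macrophage genes 16 rose (adjusted p = 0.202 and 0.265 with an estimated correlation). In all, 1481 genes differed, 907 higher and 574 lower (61.2% higher); the count was 683 without PKO replicate 1, 803 without PKO replicate 2 and 746 without DKO replicate 1. On 6 arrays it was 651 with background correction (71.3% higher) and 2293 when scaled by the median (92.7% higher, all-gene median moved by 0.30). Camera called 16 lists (10 without PKO replicate 2), and 0 with an estimated correlation.

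Against SKO, the double deletion shows what Pten loss changed where Shp2 was also lost. Sdcbp2 was at least 25.2-fold higher in DKO, Lcn2 22-fold, Gpnmb 21.2-fold, Wfdc2 19.2-fold and Cidec 18.1-fold. Falls were seen in Serpina1e (log2 -5.14), Sult2a8 (-4.68), Igfbp2 (-3.51), Cyp2c50 (-3.29) and Cyp2c37 (-3.13). Of 28 matrix genes 27 rose, and of 18 lipid droplet genes 11 rose (adjusted p = 0.178 and 0.219 with an estimated correlation), while 4 of 18 cholesterol synthesis genes fell and 0 rose (0.489). In all, 1747 genes differed, 984 higher and 763 lower (56.3% higher); the count was 902 without DKO replicate 1 and 1108 without SKO replicate 2, and 1077 in a fit of only these groups. On 6 arrays it was 609 with background correction (68.5% higher), 1163 with deposited values and 1764 when scaled by the median (87.1% higher, all-gene median moved by 0.20). Camera called 20 lists, and 0 with an estimated correlation.

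The double deletion departed from the sum of the single deletions for 461 genes, 244 above and 217 below it (limma interaction, adjusted p under the threshold). Because the interaction subtracts both single deletions, it carries any effect of Cre, which only WT lacks, with its sign reversed. Of the 461 genes, 421 were also called in DKO against PKO or SKO, where all samples carry Cre. The other 40 were called in neither and had the same sign against WT in all 3 groups with Cre. An interaction with small differences of DKO from PKO and SKO nearly forces that shared sign. It is therefore no evidence for Cre, whose effect cannot be told apart here. Fkbp5, Creld2, Nrg4, Olig1 and Sc5d were among the 40. A call in those comparisons does not clear the interactions of the 421 of Cre. Pparg, among the 421, was also higher against WT in SKO, PKO and DKO (log2 1.225, 2.10 and 1.71). Lcn2 lay above the sum by log2 4.84 ± 0.62 SE, Gpnmb by 4.43 ± 0.22, Sdcbp2 by 3.62, the ubiquitin-like gene Ubd by 3.12, Gipc2 by 2.93, S100a11 by 2.89 and Gpx3 by 2.72. Serpina1e lay below it, at -5.05 ± 0.38, as did Sult2a8 at -4.53, Gm4952 at -3.30, Fbxo21 at -3.24, Elovl3 at -3.22 and Nr1d1 at -3.01. The interaction was 0.89 at the median of 28 matrix genes, with 12 above and 0 below (adjusted p = 0.217 with an estimated correlation), and -1.20 for 17 male-biased genes, with 8 below (0.217). Elovl3 was under the detection level in DKO, Gpnmb in WT and PKO, and Sdcbp2 and Gipc2 in WT and SKO, and Serpina1e was near the top of the scale in WT and PKO, so the sizes of their interactions are not exact. These sizes rest on the brightest probe of each gene. In DKO against WT the other detected probes moved less for Gpnmb (log2 0.15, 0.57 and 0.46) and Sdcbp2 (2.84 and 1.46). In all, 74 of the 461 genes had a group under the detection level. Background left in the signal shrinks log2 differences between dim groups most, so it can enlarge or create the interactions of such genes. Camera called 18 lists, 9 without SKO replicate 2 and 0 with an estimated correlation, and fry 4. The count of genes was 218 without WT replicate 1, 282 without WT replicate 2, 180 without PKO replicate 1, 277 without PKO replicate 2 and 260 without DKO replicate 1. On 6 arrays it was 278 with deposited values, 4 with background correction, and 402 when scaled by the median (81.8% above the sum, against 52.9%; all-gene median moved by 0.18). The risen matrix genes numbered 5 or 6 without WT replicate 1 or either PKO array, and the fallen male-biased genes 4 without WT replicate 1 or PKO replicate 1.

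Genes changed by a single deletion were often changed by the double deletion. Of 212 genes higher in SKO against WT, 140 were higher in DKO, and of 133 lower genes 97 were lower, against 38.0 and 18.5 for independent lists. For PKO the shared counts were 139 and 124, against 35.2 and 19.9. SKO and PKO shared 62 higher and 40 lower genes, against 5.1 and 2.33. These comparisons share the WT arrays: log2 fold changes correlated across genes at r of 0.57, 0.60 and 0.52, where simulated unchanged groups gave 0.51, 0.50 and 0.51, and their covariances were 0.115, 0.12 and 0.0557 against simulated values of 0.0121, 0.0119 and 0.012. Set against 1 WT array each, so that none was shared, SKO and DKO shared 85 or 74 genes, PKO and DKO 96 or 45, and SKO and PKO 21 or 26, by which WT array went to which group. For SKO and DKO with WT replicate 1 and 2, 47 rose and 38 fell in both, against 10.2 and 4.51 for independent lists, with r of 0.45. With the WT arrays the other way round they numbered 40 and 34, against 7.68 and 4.13 (r of 0.48). For PKO and DKO they were 53 and 43, against 10.98 and 4.94 (r of 0.44), and 30 and 15, against 4.07 and 1.51 (r of 0.56). For SKO and PKO they were 13 and 8, against 0.322 and 0.124 (r of 0.42), and 16 and 10, against 0.656 and 0.37 (r of 0.30). Cre and array-wide differences from WT can add to these counts, and the groups tested against 1 WT array have fewer samples. Comparisons without shared arrays were SKO against WT with DKO against PKO, with 83 higher and 52 lower genes shared (23.6 and 9.37 for independent lists), 23 opposite and r of 0.36 (simulated 0.00), and PKO against WT with DKO against SKO, with 95 and 70 shared (23.7 and 13.4), 27 opposite and r of 0.39. Leaving out 1 array moved the shared counts from 237 to as few as 89 (without WT replicate 2; 91 without WT replicate 1 and 100 without SKO replicate 1), from 263 to as few as 47 (WT replicate 1; 51 without PKO replicate 1, 111 and 112 without PKO replicate 2 and WT replicate 2), from 102 to 26 without WT replicate 1 or PKO replicate 1 (42, 54 and 56 without WT replicate 2, PKO replicate 2 and SKO replicate 1), from 135 to 53 without WT replicate 2 (56, 60, 82 and 88 without WT replicate 1, SKO replicate 1, PKO replicate 1 and PKO replicate 2), and from 165 to 30 without WT replicate 1 (32, 67 and 72 without PKO replicate 1, PKO replicate 2 and WT replicate 2).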

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

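The interactions of genes and lists below came out of the planned interaction test. The count of changed genes and the fall of male-biased genes in DKO came from planned comparisons with WT. The pattern of Fkbp5 and Tsc22d3 in SKO was chosen after their values were seen. Tests of technical explanations were set out before their results were seen, apart from those named next. The rule by which 4 of them were read was changed afterwards, as stated where they are given. The tests of Cre, of DKO replicate 1 alone, of ranks within arrays, of the macrophage and endothelial difference in other settings and of glucocorticoid-induced genes without Tsc22d3 or in PKO and DKO were chosen after the results were seen.

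In 461 genes, the double deletion departed from the sum of the single ones by the limma interaction, which also carries any effect of Cre with its sign reversed. Of these, 421 were called in DKO against PKO or SKO, where all samples carry Cre. Such a call does not clear their interactions of Cre. Pparg, among the 421, was higher against WT in SKO, PKO and DKO (log2 1.225, 2.10 and 1.71). The other 40 were called in neither and had the same sign against WT in all 3 groups with Cre. Their choice nearly forces that shared sign, so it is no evidence for Cre, which stays possible for these 40. The named ones are Creld2, Fkbp5, Nrg4, Olig1 and Sc5d. The count was 218 without WT replicate 1, 282 without WT replicate 2, 180 without PKO replicate 1, 277 without PKO replicate 2 and 260 without DKO replicate 1. Of the genes named by the rule or fixed beforehand, 85 were among the 461, with 42 above the sum and 43 below it. All 85 kept their sign when each array was left out in turn, 53 kept their call in all 8 of these fits, and 32 lost it in some.

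Genes above the sum that kept their call in those fits were, as log2 interactions, Anxa2 1.59, Bicc1 1.46, Camk2b 2.44, Cbr3 1.95, Ccnd1 1.85, Cdkn1a 2.35 and Clec7a 1.43. The same held for Col1a1 1.78, Fkbp5 2.87, Gipc2 2.93, Gpnmb 4.43, Gpx3 2.72, H2-Eb1 1.38, Jun 1.06, Klf6 1.54, Lcn2 4.84, Lgals3 2.68 and Loxl1 1.37. It also held for Ly6d 2.79, Ms4a7 1.60, Orm2 2.75, S100a11 2.89, Saa2 1.41, Scara5 2.40, Sdcbp2 3.62, Slc51b 1.58, Ubd 3.12 and Wfdc2 1.94. Genes below the sum that kept their call were Abcb11 -1.10, Abcg5 -1.57, Abcg8 -2.03, Ces3b -2.48, Clstn3 -2.37, Csad -1.77, Cyp2c37 -2.33, Cyp2c50 -2.25 and Cyp2c70 -1.63. Others below it were Cyp4a12b -2.33, Elovl3 -3.22, Fbxo21 -3.24, Gm4952 -3.30, Hal -2.46, Hsd3b7 -1.33, Nr1d1 -3.01, Olig1 -2.15 and Pdia6 -1.33. The remaining ones were Pparg -1.62, Ppp1r3c -1.40, Serpina1e -5.05, Serpina7 -1.40, Slc10a1 -1.21, Sult2a8 -4.53 and Ugt2b1 -1.86.

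Of the 85 genes, 14 were under the detection level in at least 1 group, so the sizes of their interactions are not exact: Elovl3 and Hsd3b5 in DKO, Eif4ebp3 in PKO and DKO, Camk2b and Scara5 in SKO, Gipc2 and Sdcbp2 in WT and SKO, Gpnmb, Slc51b and Timp1 in WT and PKO, Col1a1, Col3a1 and Ly6d in WT, and Ms4a7 in WT, SKO and PKO. Unsubtracted background shrinks log2 differences between dim groups most, so it can enlarge or create an interaction in such genes. Serpina1e in WT and PKO and Hmgcs1 in SKO and DKO lay near the top of the scale, which compresses differences. All these interactions rest on the brightest probe of each gene. In DKO against WT, dimmer detected probes of Gpnmb, Sdcbp2, Clec7a and Cdkn1a moved less, and the other Ly6d probe moved slightly more.

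Of the 85 genes, 32 lost their call in at least 1 fit without an array, and the highest adjusted p is given with the array left out. Without PKO replicate 1 the genes above the sum were Cd74 1.46 (0.107), Cxcl14 1.22 (0.0806), Eif4ebp3 1.62 (0.0575), Lum 1.17 (0.157), Nrg4 1.71 (0.0667), Timp1 1.79 (0.0545) and Tubb2b 1.44 (0.0882). Below it were Cyp4a31 -1.83 (0.157), F7 -0.84 (0.102), Hmgcs1 -1.02 (0.0519), Irs2 -1.68 (0.0612), Mlxipl -1.14 (0.072), Tm7sf2 -0.78 (0.166) and Tpmt -3.62 (0.0976). Without WT replicate 1 they were Col3a1 0.99 (0.084), Mt1 1.48 (0.0637), Thrsp 2.65 (0.0503), Apcs -0.79 (0.0934), Apom -1.39 (0.0955), Chac1 -0.87 (0.129), Hsd3b5 -2.07 (0.0603), Sc5d -0.81 (0.129) and Slc1a2 -1.43 (0.116). Without PKO replicate 2 they were Gpx4 0.80 (0.0848), H2-Ab1 1.33 (0.0804), Hpd -0.89 (0.143), Hsd17b6 -1.48 (0.0764), Pigr -1.0 (0.0602) and Serpina4-ps1 -1.29 (0.15). Without DKO replicate 1 they were Creld2 1.52 (0.142) and H2-Aa 1.195 (0.133), and without WT replicate 2 the gene was Sucnr1 -2.48 (0.0957).

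Of the 29 gene lists, 18 had interactions past camera at the preset correlation, 0 with an estimated correlation and 4 with fry. Those that kept this in each fit without an array, with their median log2 interactions, were collagen and matrix 0.89, macrophages 0.95, cytokines and chemokines 0.53, B cells and antigen presentation 1.07, oncofetal and tumour genes 0.78, male-biased liver genes -1.20, bile acid transport -0.64, pericentral genes -0.28 (1 of 13 members called) and erythroid genes -1.22 (0 of 3 members called). Those that lost it in some were cholesterol synthesis -0.32 (adjusted p = 0.464 without SKO replicate 2 and 0.0524 without WT replicate 2) and bile acid synthesis -0.43 (0.0675 without SKO replicate 2). Without SKO replicate 2 it was also lost by the cell cycle, median 0.45 (0.0579), NRF2 genes, 0.48 (0.103), ERK targets, 0.46 (0.0675), and acute-phase genes, 0.22 (0.0988). ERK targets lost it without DKO replicate 1 as well (0.0723), and acute-phase genes without DKO replicate 1 (0.0545) or WT replicate 2 (0.0805). Xenobiotic cytochromes, -0.18, lost it without SKO replicate 2 (0.0675), PKO replicate 2 (0.0739) or WT replicate 2 (0.115). Mature hepatocyte genes, -0.15, lost it without SKO replicate 2 (0.155) or PKO replicate 2 (0.101). Periportal genes, -0.15, lost it without SKO replicate 2 (0.0851), PKO replicate 2 (0.14) or DKO replicate 2 (0.058), where their median was 0.01.

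More genes changed in the double deletion than in either single one. Quantile normalization of arrays with different signal distributions was tested as the cause, which predicted a ratio of spreads of log2 fold changes, DKO over PKO, under 1.2 without it. On scanner signals of 6 arrays scaled by the median the ratio was 1.96, and 1.71 in the deposited values. The rule written beforehand would have ruled the explanation out, but it was wrong and was changed afterwards: median scaling leaves the wider distribution of DKO replicate 1 in place, so the ratio could hardly have come out low, and it decides nothing. Ranks within arrays, which normalization leaves in place, were compared instead. Among 8148 detected genes, 1 minus the Spearman correlation with WT was 2.62 times as large for DKO as for the larger single deletion, with correlations of 0.892 to 0.92 for DKO and 0.959 to 0.97 for SKO. Over all probes, most of them under the detection level, the ratio was 1.16, which by the bound of 1.2 would fit the explanation. Both ratios were seen before the bounds were written. Among detected genes, each DKO and WT pair correlated less (at most 0.92) than each pair of a single deletion and WT (at least 0.959). Normalization cannot alter these ranks, so it did not make this lower agreement among detected genes. Genes detected on the 2 DKO arrays alone could pass the filter, and they lie near background in WT. Detected genes and all probes gave opposite readings, so the test does not decide whether normalization caused the larger count. The ratio over all probes rests mostly on probes that were not tested for change. How far normalization adds to the count of changed genes cannot be told. A lower share of hepatocytes as the whole cause of the marker rises would raise markers of other cells alike. Macrophage genes exceeded endothelial genes by a median log2 difference of 1.49 (95% bootstrap interval over genes, 10000 draws, 0.99 to 1.92). As far as 2 arrays per group allow, this argues against that, and no sort of cells was described. This interval and those given further on resample genes as if independent, so they leave out the spread between samples. The endothelial list is unstable, with a median of 0.14 on 8 arrays, 0.45 without WT replicate 1, -0.18 without WT replicate 2 and 0.48 on the deposited values of 6 arrays. The difference was 1.197 without DKO replicate 1 and 1.90 without DKO replicate 2, its lowest and highest values without an array, and on 6 arrays 1.69 with deposited values, 1.52 with median scaling and 2.37 with neqc. A smaller fall in hepatocyte share may contribute. The Cre transgene as the whole cause was tested by comparisons in which all samples carry it: 1481 genes changed in DKO against PKO and 1747 in DKO against SKO (683 without PKO replicate 1, 803 without PKO replicate 2 and 746 without DKO replicate 1 for the former, and 902 without DKO replicate 1 and 1108 without SKO replicate 2 for the latter), against 345 and 339 for the single deletions. This argues against it. DKO replicate 1 alone, the brightest of the 6 arrays with scanner signals, was tested by leaving it out: 1684 genes changed in DKO, against 390 in SKO in that fit, which argues against it. The scanner brightness of DKO replicate 2 was not determined, because the scanner columns of its position were not used. A joint effect of the deletions is the biological explanation that the design names, and it remains a hypothesis.

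Male-biased liver genes were lower in the double deletion. Female animals were tested as the cause: Xist differed by log2 0.00781 between DKO and WT and passed the detection level on 0 arrays, and the Y-linked Eif2s3y, Kdm5d and Uty differed by -0.27, -0.26 and -0.06, which argues against it. A general fall of hepatocyte transcripts as the whole cause was tested by the male-biased minus the mature hepatocyte median, -0.90 (interval -1.61 to -0.07). By the rule this spoke against it, by a narrow margin. The interval leaves out the spread between samples and nearly reaches 0, so the explanation stays open. The rule was given a further, undecided outcome after the value was seen, which did not alter what the rule gave. The Cre transgene as the whole cause was tested where all samples carry it: the male-biased median was -1.19 in DKO against PKO (interval -1.84 to -0.55) and -0.97 in DKO against SKO (-1.59 to -0.69), which argues against it. An effect of the deletions on sex-biased expression is a hypothesis that these values may support, and the diet or condition of the animals was not tested.

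Fkbp5 fell by 2.35 in SKO on the log2 scale and Tsc22d3 changed by -1.45 (adjusted p = 0.00603, and 0.0585 without WT replicate 2), genes that follow glucocorticoids and so the time of day; their choice as a pattern came after their values were seen. Collection at another clock phase was tested by 7 genes in phase with Nr1d1 minus 3 in phase with Arntl, with a median difference of -0.18 (interval -0.61 to 0.72). Nr1d1 itself was left out of the test and was higher in SKO (1.75, adjusted p = 0.00477, and 0.0523 without WT replicate 1). It was higher too in PKO (1.73, adjusted p = 0.00626, 0.0734 without WT replicate 1 and 0.0634 without PKO replicate 1), and in DKO it was at 0.47 (0.178, and 0.0321 without DKO replicate 1). The rule written beforehand would have ruled the explanation out because the interval included 0. That rule was wrong, since the interval also holds the predicted difference of 0.5, and it was changed after the result was seen: the samples and genes are too few, and a clock-phase difference cannot be told apart from an effect of the deletion. Fkbp5 was also lower in PKO, with Shp2 intact (-1.99, adjusted p = 0.00723, and 0.0865 without WT replicate 1), and in DKO (-1.47, adjusted p = 0.00482), so its fall is not specific to Shp2 deletion. A lower glucocorticoid response in SKO was tested by 8 induced genes other than Fkbp5, Tsc22d3 among them, with a median log2 change of -0.0617 (interval -0.29 to 0.01) against a predicted fall below -0.5, which argues against it as a general response; without Tsc22d3 the median was -0.02 (interval -0.22 to 0.01). In PKO and DKO the medians of the 8 genes were -0.37 (interval -0.94 to 0.24) and -0.44 (-0.72 to 0.51), which leave such a response open there. The bound for this test was also changed after the result was seen, and the earlier and later rules gave the same outcome. Cre, the time of collection and the deletions stay open as causes of the fall of Fkbp5, which all 3 groups with Cre share, and of the rise of Nr1d1.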

How the results depend on the processing

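The deposited values of 6 arrays, their scanner signals scaled by the median, a filter on their detection p and a split of the WT arrays were chosen after the data were seen; the other alternatives were planned.

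Over the alternatives that kept all arrays, used 6 or split the WT arrays, counts and shared counts stayed within 1.5 times, or Ptpn11 kept its call in SKO or DKO, in 207 comparisons; 50 counts moved and Ptpn11 in SKO lost its call once. With 1 array left out these numbers were 108 and 44. For single genes and lists, 4386 comparisons kept direction and side of the threshold, 426 lost the call, 11 gained it and 15 reversed; with 1 array left out these were 2657, 365, 7 and 19. For what moved, weakened or reversed, the cause was not tested. Settings with 6 arrays, 7, or 1 WT array per comparison leave fewer samples. That alone does not account for the gene counts with neqc. In SKO, PKO, DKO and the interaction they were lower than with the deposited values of the same 6 arrays.

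With neqc on 6 arrays, changed genes numbered 16 in SKO, 2 in PKO, 953 in DKO, 651 for DKO against PKO, 609 for DKO against SKO and 4 for the interaction, lists in SKO and PKO 11 and 12, and Ptpn11 in SKO was -1.33 (adjusted p = 0.114). Genes shared were 13 for SKO and DKO, 2 for PKO and DKO, 0 for SKO and PKO, 9 for SKO with DKO against PKO, and 2 for PKO with DKO against SKO. With median scaling they were 222, 50 and 2293 genes for SKO, PKO and DKO against PKO, 12 and 17 lists in SKO and PKO, and 41, 27 and 25 shared (PKO and DKO, SKO and PKO, PKO with DKO against SKO). With the deposited values of 6 arrays they were 159, 59, 1427, 1163 and 278 genes for SKO, PKO, DKO, DKO against SKO and the interaction, 12 lists in PKO, and 113, 42, 25, 76 and 25 shared, in the order of neqc. With only the groups compared they were 512 and 1077 genes for PKO and DKO against SKO, and 11 lists in PKO. An estimated correlation left 0 lists in each of 6 comparisons. With fry the lists numbered 0, 1 and 4 in SKO, PKO and the interaction. In DKO against WT, PKO and SKO they numbered 20, 17 and 22.

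With the WT arrays split, so that 2 comparisons shared none, shared genes were 85 for SKO and DKO with replicate 1 given to SKO and 74 with replicate 2, 96 and 45 for PKO and DKO, likewise, and 21 and 26 for SKO and PKO.

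With the replicate block, counts were 369, 340, 2552, 1473, 1724 and 465 for SKO, PKO, DKO, DKO against PKO, DKO against SKO and the interaction.

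Leaving out each array gave 118 to 390, 54 to 414, 1596 to 2720, 683 to 1630, 902 to 1574 and 180 to 554 genes in that order, and 3 to 12, 5 to 10, 14 to 20, 10 to 17, 16 to 21 and 9 to 19 lists. Shared genes were 89 to 285 (SKO and DKO), 47 to 316 (PKO and DKO), 26 to 117 (SKO and PKO), 53 to 169 (SKO with DKO against PKO) and 30 to 199 (PKO with DKO against SKO). Ptpn11 kept its call, at -1.30 to -1.14 in SKO and -1.39 to -1.15 in DKO.

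Of the genes that reversed, Tm7sf2 in DKO was the only one called on all 8 arrays. Cyclic loess gave Jun in SKO 0.0291 and Timp1 in PKO 0.0169. In SKO, neqc gave Scd1 0.16 and Jun 0.0721, median scaling Scd1 0.20 and Jun 0.16, and deposited values of 6 arrays Scd1 0.16 and Jun 0.0322. Median scaling gave Srebf1 0.015 and Egr1 0.0715 in PKO, and Tm7sf2 0.00362, Srebf1 0.38 and Igfbp1 0.017 in DKO, where it moved the median of all genes by 0.33. Egr1 in PKO was 0.0106 with deposited values of 6 arrays, and the mean of probes gave Timp1 in PKO 0.0944.

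Leaving out each array gave ranges for genes that reversed. In SKO they were Scd1 -0.22 (WT replicate 2) to 0.16 (WT replicate 1; 0.03 without SKO replicate 1), Jun -0.0448 (SKO replicate 1) to 0.0433 (SKO replicate 2; 0.0322 without WT replicate 1) and Pck1 -0.25 (WT replicate 1) to 0.11 (WT replicate 2). Fasn ran from -0.0735 (SKO replicate 2) to 0.44 (SKO replicate 1), and Igfbp1 from -0.27 and Col1a1 from -0.0646 (SKO replicate 1) to 0.58 and 0.29 (SKO replicate 2). In PKO they were Srebf1 -0.77 (PKO replicate 2) to 0.0155 (PKO replicate 1), Pck1 -0.34 (PKO replicate 2) to 0.18 (PKO replicate 1; 0.0992 without WT replicate 2) and Egr1 -0.63 (WT replicate 2) to 0.0106 (WT replicate 1; 0.00309 without PKO replicate 2). Timp1 ran from -0.093 (WT replicate 1) to 0.0808 (WT replicate 2; 0.0493 without PKO replicate 1), and Ptpn11 from -0.15 (PKO replicate 1) to 0.13 (PKO replicate 2; 0.0324 without WT replicate 2). In DKO they were Cyp7a1 -0.49 (WT replicate 2) to 0.99 (WT replicate 1) and Cyp8b1 -2.77 (DKO replicate 2, where it was called) to 0.15 (DKO replicate 1).

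Not run were no background correction, which is the main setting, median scaling of the deposited values, which already share a distribution, a slide block, as there is 1 slide, and only the groups compared for the interaction, which uses all groups. Unsubtracted background limits the folds of dim genes, which are understated. It shrinks log2 differences between dim groups most, so in the interaction it can also enlarge or create a departure from the sum.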

Other observations

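The genes in this part were chosen after their values were seen, as were the tests of their neighbours, and no explanation was tested.

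In SKO, 2 genes with several probes stood out by probe. The mean log2 signals of the 2 Rpl29 probes in WT, SKO, PKO and DKO were 11.24, 8.0, 10.81 and 9.84, and 12.71, 11.08, 12.72 and 12.05, with 2 arrays per group. For Epm2aip1 the brightest probe had 9.65, 7.92, 10.08 and 9.36, and the others 8.37, 7.93, 8.31 and 8.19, and 8.35, 8.32, 8.62 and 8.56. Of the 100 tested genes nearest to Rpl29 in gene order, 8 changed in SKO, against 4.24% of all tested genes, with p = 0.0603 by an exact hypergeometric test. Of the 100 nearest to Ptpn11, 9 changed, with p = 0.0251 by the same exact hypergeometric test. Neighbouring genes are not independent, which these p-values do not take into account.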
